A study of Caenorhabditis elegans with 2 samples.

How the data were processed

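The data came from chromatin immunoprecipitation followed by sequencing (ChIP-seq) of whole young adult Caenorhabditis elegans hermaphrodites. Per the labels, worms of strain OP399 carried an integrated transgene, wgIs399, in an unc-119 mutant background and expressed F22D6.2 with GFP and FLAG at its C-terminus. The annotation used here lists F22D6.2 under the symbol mstr-1. Worms were collected 67 hours after synchronization as starved L1 larvae, chromatin was sonicated, and tagged protein was recovered with an antibody against GFP. The labels number the 2 samples as biological replicates 1 and 2 of 1 group. No other condition was analysed here, so each test compared sites or genes within the peak lists, and no test compared groups of samples.

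The authors deposited 8 peak lists, 4 on genome build ce10 and 4 on ce11. For each build there was a list for each replicate, a list made from both replicates together, and a thresholded set. Per the labels, the first 3 kinds held peaks and background regions meant as input to an irreproducible discovery rate (IDR) step, and the last held the peaks that passed it. Per the file descriptions deposited with the samples, each list was made from the replicate's or both replicates' alignments with a control, and the same control served both replicates. The aligner, the peak caller, their versions and the IDR threshold were not given in the sources used here. Each deposited signal value is the peak caller's own value for a peak over the control, and its scale was not given. It was used only to rank, filter and describe peaks within a list. The deposited −log10 q-value reached a ceiling of 2.44 in all 798 thresholded ce11 peaks and could not rank them. The deposited offset of each summit from the start of its peak gave the summit's position. The number of reads was not given in these files, so the depth of each sample was unknown, and no interval that needs it was computed.

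Coordinates are given on ce11 and counted from 1. Gene models came from Ensembl release 115 for WBcel235, the same assembly as ce11, and sequence from the RefSeq copy of that assembly. No annotation of ce10 was used here, so the ce10 lists entered only counts, widths, values and replicate overlaps. Coordinates were not converted between builds.

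Each deposited summit was counted as a peak, so a region with several summits counted more than once. A summit was called shared between lists when another lay within 100 bp. Replicates were compared over as many of each one's peaks with the highest signal value as the thresholded set held. Chance was set by placing peaks at random within their own chromosome 1000 times (200 times where whole intervals were overlapped as an alternative), or by drawing as many of replicate 2's listed regions per chromosome, so that 0.001 was the smallest one-sided and 0.002 the smallest two-sided permutation p. Each summit was put in 1 of 10 annotation classes. The order was within 500 bp of the 5' end of a protein-coding gene, within 200 bp of a tRNA, snRNA, snoRNA, rRNA or other non-coding RNA gene, coding exon, UTR, intron, and intergenic. A gene was called bound when a thresholded summit lay within 500 bp of its annotated 5' end on either side. The 28 lists of protein-coding genes were each tested against all other protein-coding genes and 9 RNA classes against all other genes. These tests were two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over all 37. Fisher's exact tests also compared X with autosomes, the middle of 3 equal parts of each autosome with the outer parts, and divergent with other promoters, adjusted over these 3 tests. A promoter was divergent when a 5' end on the other strand, pointing away, lay within 1000 bp. Each of 2080 6-mers, with reverse complements joined, was tested for presence in the central 100 bp against both 100 bp flanks starting 200 bp from the summit. Intervals of odds ratios are exact 95% intervals. Genes and peaks are not independent replicates, and these p-values do not measure spread between animals.

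The choices above, the gene lists and the rule for named genes were set before the data were examined, except the chance value drawn from listed regions, which was added afterwards. The rule took protein-coding genes within 500 bp of the 25 thresholded peaks with the highest signal value, up to 4 members with the highest peak signal of each list or RNA class that passed its test, F22D6.2 and unc-119, and the 5 enriched 6-mers with the smallest p. Nuclear peaks named by rank outside this rule were chosen after their values were seen, because mitochondrial peaks filled most of the top 25. The functions were tested on simulated data made from the thresholded ce11 set. In randomly placed sets, 0 of 560 tests of protein-coding gene lists, 0 of 50 tests of annotation classes and 0 of 10400 6-mer tests (higher at centres) passed. The tests of RNA gene classes were not checked in this way. Planted gene lists were recovered in 60 of 60 cases, and a planted 6-mer led the table in 5 of 5 sets. Each planted list was given more peaks than any coding list had bound genes in the real set. Its recovery therefore does not show that effects of the real sizes would be found. Random placement also does not keep the difference in G and C between real centres and flanks, so the 6-mer check does not cover it.

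Alternatives covered the window, the overlap definition and its chance value, a stricter peak set, each replicate alone, the ce10 lists, the background of the gene lists, assignment to the nearest gene and the background of the 6-mers. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.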

Results

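F22D6.2 fused to GFP was mapped by ChIP-seq in whole young adult hermaphrodites, with 1 group of 2 biological replicates. The deposited lists held 25000 regions for replicate 1, 23268 for replicate 2 and 26002 for both replicates pooled on ce11. Of these, 798 peaks passed the authors' threshold, with a median width of 436 bp. Their signal value, as the authors deposited it, ranged from 80.3 to 6333 with a median of 111. The depth of the libraries was unknown. The design implied a map of binding sites and a comparison of the replicates, with no contrast between conditions.

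Many of the same sites ranked high in both replicates. Of the 798 highest peaks of replicate 1, 470 (58.9%) had a summit within 100 bp among the 798 highest of replicate 2, against a mean of 0.732% under random placement (one-sided permutation p = 0.001, the smallest possible). Against regions drawn at random from all those listed for replicate 2, the mean was 5.07% (one-sided permutation p = 0.001), a comparison added after the overlap was seen. The same control served both lists, and neither chance value allows for signal that it shared. Of the thresholded peaks, 77.2% lay among the highest of replicate 1, 78.8% among those of replicate 2 and 22 in neither. That set is the top of the list pooled from both replicates, so these shares follow in part from its construction. Among 752 thresholded peaks matched in both lists, Spearman's rho of the signal value was 0.498 (bootstrap 95% interval 0.430 to 0.561), a description across peaks, which are not independent. The peak upstream of rpl-3, a ribosomal protein gene, was at rank 17 in replicate 1 and rank 19 in replicate 2. The peak at eef-2, a translation elongation factor gene, was at rank 245 and rank 1061.

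**Figure D1:**
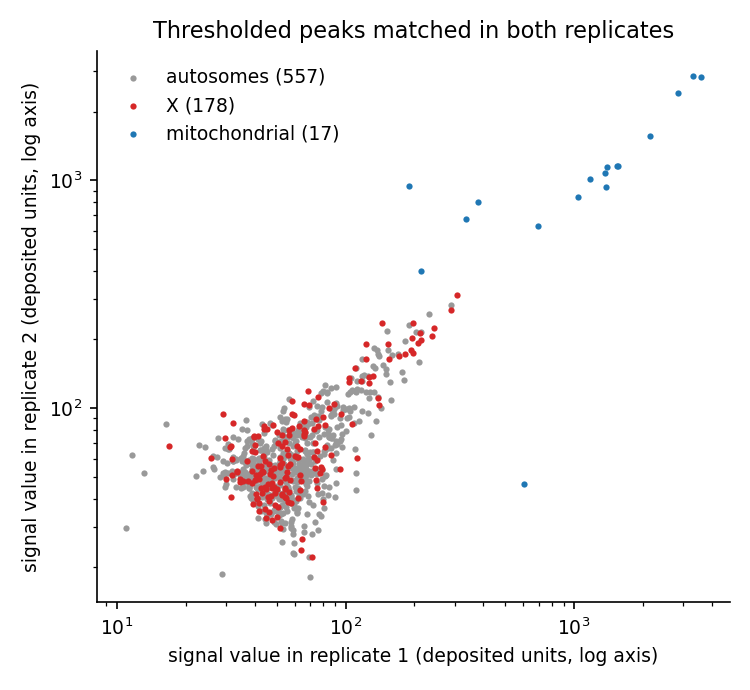
Signal value of each thresholded peak in replicate 1 (x axis) and replicate 2 (y axis), both in deposited units on log axes, with 1 point per peak matched in both lists and colours for autosomes, X and the mitochondrial genome. Most mitochondrial peaks lie above all nuclear ones, and Spearman's rho over the 752 peaks was 0.498.

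The locus of the tagged gene itself held more listed regions than an even spread in every ce11 list. It and unc-119 were examined because the transgene was taken to carry F22D6.2 and an unc-119 rescue. Extra copies of a locus can raise signal there, and this was not told apart from binding. F22D6.2 (mstr-1, WBGene00009050) lies on chromosome I from 7079562 to 7082040 on the minus strand. Within 20 kb of it, 24 regions were listed in the pooled list against 11 for an even spread over the nuclear genome, and 22 in each replicate. Of these, 2 passed the threshold. The higher one, from 7079423 to 7079704 with its summit at 7079588, lay at the 3' end of mstr-1 and 13 bp upstream of the 5' end of kin-14, with a signal value of 161. The nearest summit within 100 bp of it was at rank 88 in replicate 1 and rank 804 in replicate 2. In replicate 2 the highest summit of the locus lay at 7079384, at rank 189. The other thresholded peak, from 7082805 to 7083240, was intergenic, 983 bp upstream of mstr-1, with a signal value of 101. It was at rank 919 in replicate 1 and rank 282 in replicate 2. No thresholded peak lay within 20 kb of unc-119, on chromosome III from 10902641 to 10908935. There the pooled list held 5 regions against 12 for an even spread, replicate 1 held 13 against 11.5 and replicate 2 held 7 against 10.7. The highest pooled one had a signal value of 25.7.

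Summits gathered at promoters and at small structured RNA genes, and were sparse in gene bodies. Of the 798 summits, 343 (43%) lay within 500 bp of the 5' end of a protein-coding gene, against 19.6% under random placement (one-sided permutation p = 0.001). A further 61 (7.64%) lay at tRNA genes against 0.427%, 40 (5.01%) at snoRNA genes against 0.143%, and 15 (1.88%) at snRNA genes against 0.0516%. Coding exons held 22 summits (2.76% against 18.5%) and introns 74 (9.27% against 26.5%). All of these classes passed the two-sided permutation test, adjusted p = 0.0029. Other non-coding RNA genes were also above random placement (7.77% against 5.47%, permutation adjusted p = 0.0111). UTRs were below it (1.5% against 2.96%, permutation adjusted p = 0.005), as was intergenic sequence (21.1% against 26.3%, permutation adjusted p = 0.0029). The UTR call was lost in either replicate alone, and the intergenic call was lost in the stricter set, in replicate 2 alone and with a 250 bp window, where the share turned to above random placement (29.3%, permutation p = 0.943). Of nuclear summits alone, 42.4% lay within 500 bp of a protein-coding 5' end, against 18.4% under random placement. Among the 330 nuclear summits near a 5' end, 289 (87.6%) lay upstream of it, and the middle 50% of offsets ran from 66.3 to 281 bp upstream.

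**Figure D2:**
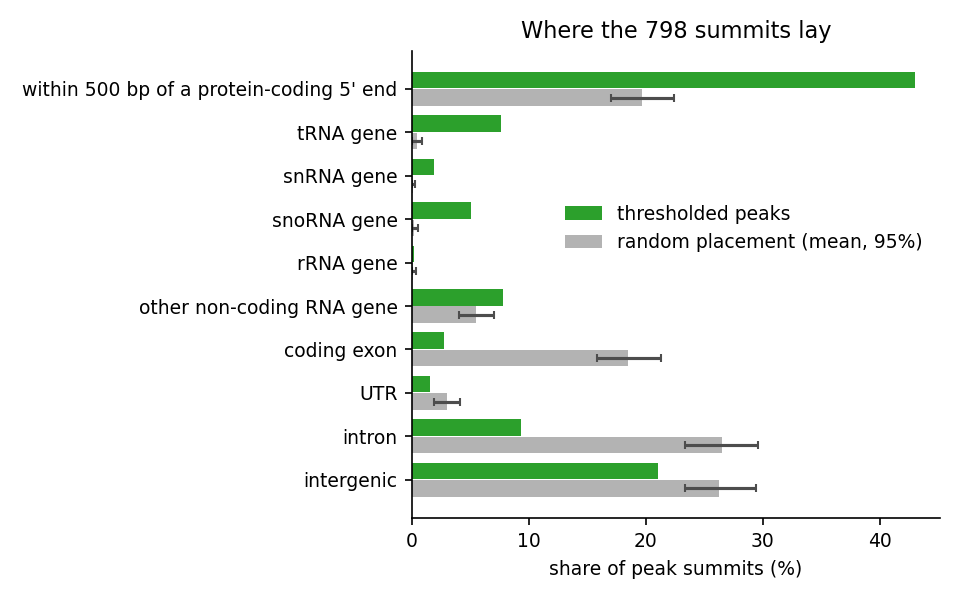
Share of the 798 thresholded summits in each annotation class (green bars, x axis in percent) beside the mean of 1000 random placements (grey bars, with the central 95% of placements as error bars). Promoters, tRNA, snoRNA and snRNA genes exceed random placement, at 43%, 7.64%, 5.01% and 1.88%, while coding exons (2.76%) and introns (9.27%) fall below it.

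The highest peaks were mitochondrial. Of the 25 highest, 18 lay on the 13794 bp mitochondrial genome, which held 20 thresholded peaks in all with signal values from 259 to 6333. Each summit was counted as a peak: the 20 lay in 12 distinct regions, as did the 18, and all 798 peaks in 787. The highest, from 12049 to 12773, lay in a coding exon. Those within 500 bp of a mitochondrial 5' end marked MTCE.21 and COX3, with signal values of 6155 and 5229, and the latter peak also marked MTCE.25. Lower ones marked the pair MTCE.12 and ND1 (2518), MTCE.34 (2437), MTCE.26 (2284) and MTCE.16 (1800). COX3 and ND1 encode respiratory chain subunits. Of the 20 mitochondrial summits, 13 lay within 500 bp of a protein-coding 5' end. Annotated genes lie close together there, and no chance share was computed for this genome alone. The genes named here therefore do not show a preference of mitochondrial summits for 5' ends.

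The only nuclear gene named by the 25 highest peaks was rpl-3 (WBGene00004414), which encodes a protein of the large ribosomal subunit. Its peak, on chromosome III from 3867363 to 3867761, had its summit 275 bp upstream of the 5' end and a signal value of 569.8. The other nuclear peaks are described here after their values were seen. The highest of all nuclear peaks was intergenic on X, from 11093902 to 11094428, with a signal value of 623. On X a further one lay in an intron of mom-1, from 6296297 to 6296817 (538), and on chromosome III one lay in an intron of pqn-41, from 1925034 to 1925549 (491). Next at promoters came the peak between rpl-20 and Y17G9B.5 (432), those at tasp-1 (419) and at cdc-48.1 (374), which encodes an AAA ATPase, and the one between drr-2 and set-16 (348).

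Lists of cytosolic ribosomal proteins, translation factors, respiratory chain, chromatin regulator, heat shock and chaperonin CCT genes were bound more often than other protein-coding genes. Of 19985 protein-coding genes, 411 (2.06%) were bound, 403 of them on nuclear chromosomes. Cytosolic ribosomal protein genes were bound in 16 of 83 cases (19.3%, odds ratio 11.8, 95% interval 6.32 to 20.8, Fisher's exact test adjusted p = 8.33e-11). The highest signal values were at rpl-3 (569.8), rpl-20 (432), rpl-35 (317) and rpl-12 (311). Translation initiation and elongation factor genes were bound in 7 of 39 cases (odds ratio 10.6, 95% interval 3.92 to 24.6, Fisher's exact test adjusted p = 5.96e-05), led by iff-2 (249), eif-3.C (161), eef-1G (138) and eef-2 (117). Respiratory chain and ATP synthase genes were bound in 7 of 52 cases (odds ratio 7.52, 95% interval 2.84 to 16.9, Fisher's exact test adjusted p = 0.000329), among them cox-5A (300.03), atp-1 (154), cox-5B (110.4) and mev-1 (110.1).

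Chromatin and synMuv regulator genes were bound in 8 of 60 cases (odds ratio 7.45, 95% interval 3.04 to 15.9, Fisher's exact test adjusted p = 0.000123). Their highest signal values were at lin-54 (311), lin-53 (159), lin-9 (159) and lin-35 (137). Of these, lin-35 encodes the worm retinoblastoma protein, and lin-54 shares its summit with the divergent gene rpl-12. Heat shock and stress protein genes were bound in 6 of 55 cases (odds ratio 5.90, 95% interval 2.05 to 13.9, Fisher's exact test adjusted p = 0.00304), with dnj-9 (204), hsp-1 (192), hsp-110 (192) and hsp-3 (186) the highest. The chaperonin CCT was marked at 2 of 8 genes, cct-8 (202) and cct-1 (120.0), with an odds ratio of 15.9 (95% interval 1.57 to 89.5, Fisher's exact test adjusted p = 0.0336). A summit marks every gene within 500 bp, so a neighbour of a gene named here can share its peak.

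Chemoreceptor genes, which act in sensory neurons, were bound less often than other genes. Only 3 of 1293 carried a peak (0.232% against 2.18%, odds ratio 0.104, 95% interval 0.0214 to 0.307, Fisher's exact test adjusted p = 3.98e-08), namely sri-5, srh-16 and srh-269. The marker lists for neurons (0 of 108), muscle of the body wall (0 of 43), intestine (0 of 44), pharynx (0 of 29) and hypodermis (0 of 40) held no bound gene, and none passed the exact test. Upper 95% bounds of their odds ratios ran from 1.65 (neurons) to 6.48 (pharynx), so these lists do not show a lower share. The list of meiotic chromosome proteins also held none (0 of 54), and that of homeobox genes 0 of 98, with vacuolar ATPase subunits at 0 of 21. Germline and oogenesis markers were bound in 2 of 57 cases, genes of sperm proteins and spermatogenesis in 1 of 86 and cuticle collagens in 2 of 176. Splicing factors were bound in 5 of 75 cases (Fisher's exact test adjusted p = 0.0545). The other lists that did not pass were mitochondrial ribosomal proteins (3 of 70), aminoacyl-tRNA synthetases (1 of 31), proteasome subunits (2 of 33), core histones (1 of 81), cell cycle and replication (4 of 98), nuclear hormone receptors (7 of 274), C-type lectins (1 of 240), F-box and MATH-BTB families (3 of 412) and general transcription (3 of 83).

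The size of these differences depended on the background. Against the 3232 protein-coding genes (16.2%) that were bound or had any listed region near the 5' end in both replicates, the odds ratios of the 6 higher lists were smaller, that of chemoreceptors was closer to 1, and only the ribosomal list passed (16 of 49, odds ratio 3.42, 95% interval 1.74 to 6.46, Fisher's exact test adjusted p = 0.00597). The lists held fewer genes there. Translation factors had an odds ratio of 4.42 (95% interval 1.45 to 12.6, 7 of 18), chromatin regulators 2.78 (1.05 to 6.64, 8 of 28), respiration 2.86 (0.995 to 7.30, 7 of 24), heat shock 2.44 (0.784 to 6.54, 6 of 23) and the chaperonin CCT 6.89 (0.498 to 95.2, 2 of 4). Their adjusted p ran from 0.0647 to 0.379 by Fisher's exact test. Chemoreceptors had one of 0.464 (95% interval 0.0918 to 1.46, 3 of 47). With only the 3225 genes that had a listed region in both replicates, 404 of them bound, the ribosomal list again was the only one to pass (odds ratio 3.48, Fisher's exact test adjusted p = 0.00499).

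Other choices moved single lists. With a 250 bp window only 5 of 83 ribosomal genes were bound (odds ratio 5.12, Fisher's exact test adjusted p = 0.0182), and with each summit given only to its nearest gene 10 were (odds ratio 8.33, Fisher's exact test adjusted p = 8.60e-06). No CCT gene was bound with the nearest gene only. The CCT and heat shock lists did not pass with a 250 bp window (Fisher's exact test adjusted p = 0.222 and 0.107), CCT did not with a longer set, the 1195 highest pooled peaks (0.0525), and respiration did not in the stricter set (0.243). Lists that passed only elsewhere were splicing factors, with a 1000 bp window, in the longer set and in replicate 2 alone (Fisher's exact test adjusted p = 0.0471, 0.00589 and 0.00877), and cell cycle genes, in the longer set and in replicate 1 alone (0.00824 and 0.0344). C-type lectins and F-box and MATH-BTB families were lower with a 1000 bp window (0.0445 for each) and in the longer set (0.0290 and 0.0223).

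**Figure D3:**
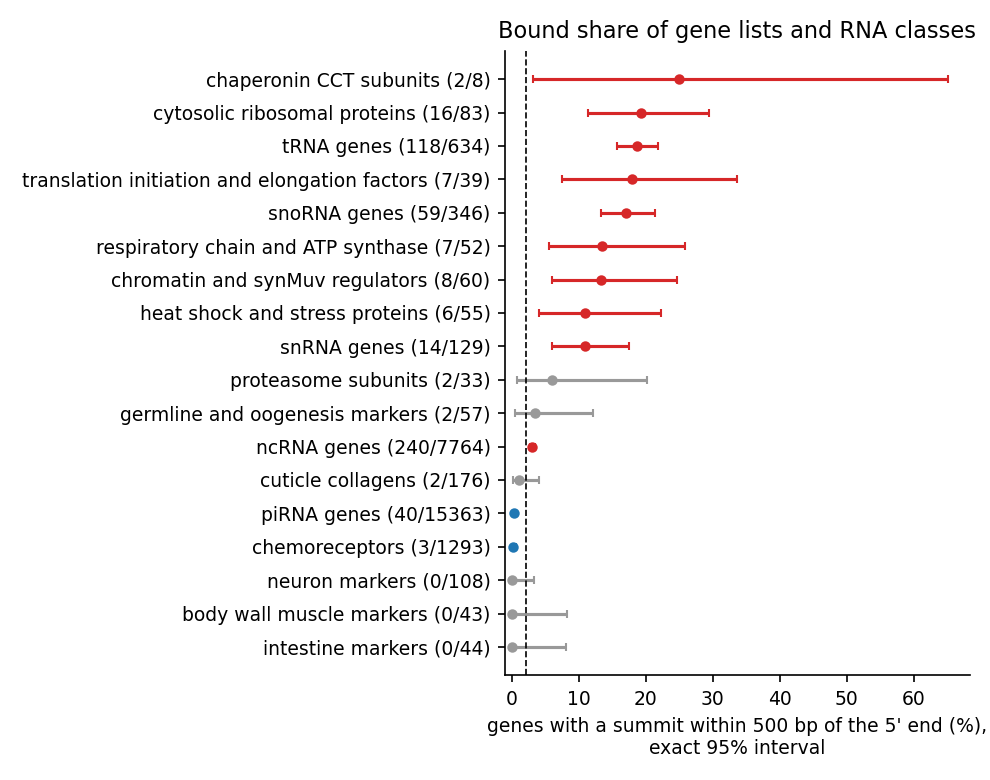
Share of genes bound (x axis, percent) in the lists and RNA classes that passed, and in a selection of lists that did not. Bound and total genes stand beside each name, with exact 95% intervals as bars. Other lists and classes that did not pass are not drawn. Red marks lists above and blue lists below the other genes by Fisher's exact test, and grey lists did not pass. The dashed line is the 2.06% of all protein-coding genes, while RNA classes were tested against all other genes.

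Genes for tRNAs, snoRNAs and snRNAs were bound far more often than other genes. The reference was all other genes, among them 15363 piRNA genes that were rarely bound. The backgrounds of genes with a listed region, which weakened the coding lists, were not applied to the RNA classes. A thresholded summit lay within 500 bp of the 5' end of 118 of 634 tRNA genes (18.6%, odds ratio 13.2, 95% interval 10.6 to 16.4, Fisher's exact test adjusted p = 4.57e-78). The tRNA genes with the highest signal were mitochondrial, MTCE.17, MTCE.18, MTCE.19 and MTCE.20, which share 1 peak (6155). Without mitochondrial peaks, 99 tRNA genes were bound and the odds ratio was 10.8. Of 346 snoRNA genes, 59 were bound (17.1%, odds ratio 11.1, 95% interval 8.18 to 14.9, Fisher's exact test adjusted p = 1.75e-36), led by ZK994.7 (266), the neighbours C51F7.3 and C51F7.4 (253) and F59C6.15 (173). Of 129 snRNA genes, 14 were bound (10.9%, odds ratio 6.27, 95% interval 3.31 to 11, Fisher's exact test adjusted p = 1.19e-06). The highest were sls-2.1 (362) and sls-2.4 (311), genes for the spliced leader RNA SL2, then sup-6 (197) and R07E5.16 (191).

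Genes annotated only as ncRNA were bound in 240 of 7764 cases (3.09%, odds ratio 1.85, Fisher's exact test adjusted p = 1.83e-13), with C18A11.13 (394), R03E9.10 and R03E9.7 (379) and H37A05.6 (328) the highest. Of all other genes 1.70% were bound, but these include the 15363 piRNA genes, of which only 0.260% were. Of all genes other than piRNA genes, with the ncRNA genes included, 865 of 31563 (2.74%) were bound, close to the 3.09% of ncRNA genes. Much of the odds ratio of 1.85 therefore came from the piRNA genes in the reference. A reference without piRNA genes, which would lower this odds ratio, was not tested. The small piRNA genes were bound less often, in 40 of 15363 cases (0.260%, odds ratio 0.0926, Fisher's exact test adjusted p = 9.07e-99). The odds ratio was 0.0442 with a 250 bp window and 0.193 with a 1000 bp window, where 14 and 108 were bound. Of the piRNA genes, 21ur-11723 had the highest signal value (249), ahead of 21ur-12748 and 21ur-865 (164) and 21ur-12279 (154). The remaining classes did not pass, with 2 of 22 rRNA, 10 of 261 miRNA, 5 of 194 lincRNA and 1 of 100 antisense RNA genes bound. The miRNA class passed with a 1000 bp window (16 of 261, Fisher's exact test adjusted p = 0.00467) and in replicate 1 alone (12 of 261, Fisher's exact test adjusted p = 0.0135). RNA genes often lie in clusters or next to coding genes, so 1 summit can mark several of them, and a stretch without summits can leave several unbound. Such neighbours, like 21ur-12748 and 21ur-865, which overlap, were counted as independent genes. The p-values of these classes, that of the piRNA genes above all, are therefore too small to be read at face value.

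The share of bound protein-coding genes did not differ measurably between X and autosomes. On X, 53 of 2731 protein-coding genes were bound (1.94%) and on autosomes 350 of 17242 (2.03%), an odds ratio of 0.955 (95% interval 0.70 to 1.28, Fisher's exact test adjusted p = 0.826). Autosome centres and arms did not differ measurably either, at 2.10% and 1.99% (odds ratio 1.06, 95% interval 0.846 to 1.32, Fisher's exact test adjusted p = 0.826). Genes with a divergent neighbour were bound in 171 of 3539 cases (4.83%) and others in 240 of 16446 (1.46%), an odds ratio of 3.43 (95% interval 2.79 to 4.20, Fisher's exact test adjusted p = 9.01e-30). A summit between divergent genes marks both, as at rpl-12 and lin-54, which raises this ratio by construction.

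Peaks were spread unevenly over the chromosomes. X held 189 of 778 nuclear thresholded peaks (24.3%, exact binomial 95% interval 21.3% to 27.5%) on 17.7% of the nuclear genome (exact binomial p = 3.79e-06), a comparison chosen after the counts were seen. Chromosome III also held more than its share of the genome, 16.3% (95% interval 13.8% to 19.1%) on 13.7%. Chromosomes IV and V held less, at 14.01% (11.6% to 16.6%) on 17.4% and 16.3% (13.8% to 19.1%) on 20.9%. Without the 79 nuclear peaks at tRNA genes, 53 of them on X, the X share was 19.5% and the exact binomial p 0.215. These 79 are all summits within 200 bp of a tRNA gene, also those put in the class near a protein-coding 5' end. On X, 46 summits (24.3%) were in the tRNA class and 49 (25.9%) near protein-coding 5' ends, while on autosomes these shares were 2.38% and 47.7%.

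**Figure D4:**
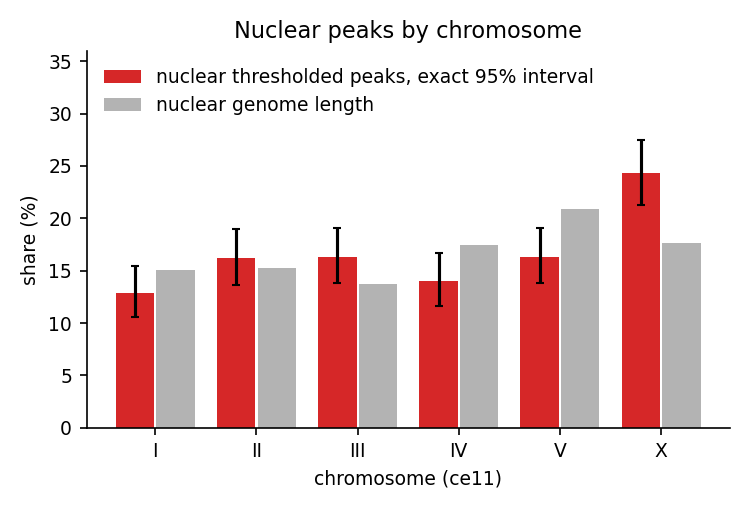
Share of the 778 nuclear thresholded peaks on each chromosome (red bars, percent, with exact 95% intervals) beside the chromosome's share of the nuclear genome (grey bars). X holds 24.3% of the peaks on 17.7% of the genome.

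Summit centres were rich in G and C and in particular 6-mers. The central 100 bp had 47.2% G and C against 35.7% in the flanks, and of 2080 6-mers 512 were more frequent at centres and 315 less frequent. The leading ones at centres were GACGCA, in 15.3% of centres and 2.44% of flanks (Fisher's exact test adjusted p = 4.05e-27), ACGCAG (15.04% and 2.57%), ACGCGC (11.5% and 1.44%), CGAGAG (14.3% and 2.94%) and GAGAGA (21.2% and 7.02%), the last with a Fisher's exact test adjusted p of 2.01e-20. GACGCA and ACGCAG overlap by 5 bases. Against shuffled sequences with the same dinucleotide counts, 126 6-mers were more frequent at centres, led by GAGAAA (22.2% and 9.65%). These 5 were among them, but their shares were higher in shuffled sequences than in flanks: 5.51% for GACGCA, 5.01% for ACGCAG, 6.83% for CGAGAG, 9.90% for GAGAGA and 7.96% for ACGCGC. The last was close to the threshold (Fisher's exact test adjusted p = 0.0452).

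The ce10 lists gave a longer thresholded set of 1195 peaks. Both sets were exactly the top of their pooled list: all 798 ce11 peaks were the pooled ce11 regions with signal values of at least 80.3, and all 1195 ce10 peaks those of at least 66.1. Per chromosome the shares were alike, with X holding 24.3% of nuclear peaks on ce11 and 23.7% on ce10, and the mitochondrial genome 20 peaks on each. Whether the same sites led both was not tested.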

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

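The sets of nuclear, X or autosomal peaks only, the longer ce11 set and the set without tRNA peaks were chosen after seeing the data; the other alternatives were set before. The chance value from listed regions and the background of listed genes only were added afterwards too. Ranking by q-value was not counted: 1480 and 1037 peaks of the replicates shared the ceiling, so the same 798 were kept. Of 80 alternative values of the main results, 68 kept their direction and side of the threshold, or stayed within the bootstrap interval (rho) or within 1.5 times (counts). That margin took in 1195 peaks on ce10 against 798, and 4 higher coding lists against 6 with a 250 bp window. For overlaps of peaks between lists, any overlap counted as the same direction, so these values could not reverse. The value with chance from listed regions repeated the same overlap. The stricter set held 399 peaks by construction, and in it rho between replicates was 0.578 and 309 6-mers passed. The number of enriched 6-mers was 152 in the central 60 bp, 126 against shuffled sequences and 129 in X peaks only, where fewer peaks entered; for the others the cause was not tested. Lists of coding genes that were higher numbered 6, and 1 with either background of genes with a listed region, where odds ratios were smaller and lists held fewer genes. Without peaks at tRNA genes the X share was 19.5% and no longer passed. In either replicate alone, the share of summits near a 5' end lay between 39.6% and 40.9%. Intergenic summits made up 29.3% with a 250 bp window, above random placement but not passing (permutation p = 0.943), since the promoter class was narrower; the odds ratio of the chaperonin CCT list was 0 with the nearest gene only. Nuclear peaks held 0% in the rRNA class. Odds ratios near 1 that had not passed crossed it: X against autosomes was 1.01 with a 1000 bp window and 0.746 to 1.04 in either replicate alone, and centres against arms 0.97 to 1.16. Gene positions on ce10 were not run, as no annotation of that build was used here. No paired analysis was possible because there was 1 group of samples. The depth was unknown, so what it limits was not measured.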

Other observations

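The tests of tRNA genes on X against autosomes, of SL2 genes, of mitochondrial coverage, of the X share without tRNA peaks, overall and among the 50 highest, of motif matches at peaks and of genes with a listed region only were chosen after the result or related values had been seen. The tests of mitochondrial summit positions, of motif matches on autosomes and of promoters that were bound or had a listed region were set before their results were seen.

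Bound small RNA genes fell unevenly over the genome. Among nuclear tRNA genes, 68 of 276 on X were bound (24.6%) and 31 of 336 on autosomes (9.23%), an odds ratio of 3.21 (95% interval 1.99 to 5.27, Fisher's exact test p = 2.84e-07). The snoRNA genes showed other counts, with 1 of 33 bound on X and 58 of 313 on autosomes, a difference that was not tested. Within the snRNA class, 7 of 18 genes of the spliced leader SL2, which is spliced onto downstream genes of operons, were bound, and 7 of the 111 other snRNA genes (odds ratio 9.17, 95% interval 2.30 to 37.6, Fisher's exact test p = 0.000608).

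X was most strongly represented among the highest nuclear peaks, with 20 of the 50 highest (40.0%, exact binomial 95% interval 26.4% to 54.8%) and 189 of all 778. Of the 25 highest X peaks, 21 had their summit outside protein-coding genes. Several held the motif TCGCGCAGGGAG, known from the sites that recruit the dosage compensation complex to X. An exact match lay on X from 11094123 to 11094134, on the minus strand, within the highest nuclear peak. Another lay from 2997121 to 2997132, in Y41G9A.17. Of the 25, 13 had a match of at most 2 mismatches within 100 bp and 10 one of at most 1, such as TCGCGCAGGGAA from 6296574 to 6296585 in mom-1. The 6-mers with the smallest p in X peaks, CCTGCG (12.7% of centres, 0.794% of flanks) and CCCTGC (13.2% and 1.32%), are the reverse complements of CGCAGG and GCAGGG, which are parts of this motif. CCTCTC, which is not a part of it, had the same counts and p as CCCTGC. These shares covered all 189 X peaks, also the 25 in which the motif was noticed. They were not rerun without those 25, or against shuffled sequences for X alone.

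For the excess of peaks on X, peaks at tRNA genes may account for much of it, since the X share without them was 19.5% (exact binomial 95% interval 16.6% to 22.6%), an interval that holds the 17.7% of the genome. They do not account for the top of the list: none of the 50 highest nuclear peaks lay at a tRNA gene, and X held 40.0% of these 50 (exact binomial 95% interval 26.4% to 54.8%). Sites with the recruitment motif, as matched here, are a further candidate explanation for a part of the excess at most, since most X peaks held no match. The test compared the shares of X and autosomal peaks with a match. It did not measure how much of the excess such peaks make up. Of 189 X peaks 19 had a match of at most 2 mismatches, but 13 of these are the peaks in which the motif was noticed. Among the other 164 X peaks, 6 had one, and 4 of 589 autosomal peaks (odds ratio 5.54, 95% interval 1.30 to 27.01, Fisher's exact test p = 0.00941). With at most 1 mismatch the counts were 2 of 164 and 0 of 589. The lower 95% bound of that odds ratio was 0.676 (Fisher's exact test p = 0.0472). The autosomes argue against the motif sequence alone: 0 of 37 genomic matches there with at most 1 mismatch had a thresholded summit within 100 bp. On X 16 of 32 had one, with a lower 95% bound of 7.45 on the odds ratio (Fisher's exact test p = 3.14e-07). This test counted matches at the same peak separately. It was not rerun without the 25 highest X peaks, in which the motif was noticed. Of the 12 X peaks at which the 16 matches lay, only 2 were outside those 25. Whether the tagged protein binds there itself, or open chromatin at such sites is recovered with any antibody, stays open, as no other factor or untagged strain was analysed here. With 1 group in the design, no comparison of conditions tested a biological explanation.

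For the mitochondrial peaks, raised signal over the whole mitochondrial genome, as from its many copies, is a candidate explanation that these lists cannot settle. Thresholded peaks covered 58.9% of it. The pooled list, which reached down to a signal value of 15.1, held the same 20 mitochondrial peaks and no other. Raised signal over the rest of that genome was therefore not shown. Background without fixed positions was argued against, since 14 of 19 mitochondrial summits of replicate 1 lay within 50 bp of one of replicate 2, against a mean of 2.63 under random placement (permutation p = 0.001, the smallest possible). Uneven recovery of mitochondrial DNA that is the same in each library would give fixed positions too and stays open. No biological explanation was tested.

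For the ribosomal protein genes, recovery of any promoter with a detectable region, to the same extent, was argued against as the whole account, since among genes that were bound or had a listed region in both replicates the odds ratio was still 3.42 (95% interval 1.74 to 6.46). Without the bound genes that had no such region it was 3.48 (95% interval 1.77 to 6.58). Recovery that grows with how open or active a promoter is stays open, as chromatin accessibility and expression were not analysed here. No biological explanation was tested.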
